A study of Mus musculus with 12 samples.

How the data were processed

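Gene expression was measured in whole retina of male C57BL/6J mice with 1 array per animal, for 6 animals made diabetic with streptozotocin, a toxin of the insulin-producing cells of the pancreas, and for 6 normoglycaemic controls of the same age. Per the labels' protocols, streptozotocin was injected once into the peritoneum at 160 mg/kg in mice of 8 weeks and 24 to 26 g, and a blood glucose above 15 mM was required 7 days later. Animals were killed at 6 weeks, while the series text calls the diabetic animals 6 weeks old, which an injection at 8 weeks does not allow, so the age and the duration of diabetes are not settled here. Per the labels' protocols, eyes were snap frozen, the retina was taken from the frozen eye, RNA was extracted with Trizol and biotinylated cRNA was prepared by the Affymetrix procedure. Body weights and glucose values of single animals were not used here.

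The deposited table held log2 values made with RMA (robust multi-array average, which corrects background, normalizes quantiles and summarizes probes), per the submitters' processing notes. The version of RMA, the name of the array and the probe set definition were not given in the sources used here. Each of the 24973 lines of the table stood for 1 Entrez gene number. The sorted values of the 12 arrays were identical (largest difference 0), with a median of 5.73 and a range from 5.07 to 14.10, so that no scaling between arrays could be compared and a gene at the top of the range had little room to differ. Because the log2 values of all arrays were forced onto 1 distribution, a change of most genes in 1 direction would not be visible.

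Gene numbers were named with the platform annotation (24015 lines) and, for 559 more, with the RefSeq table of assembly GRCm38.p6, and symbols were updated through the gene number. The remaining 399 lines had no name and were left out. For 4 symbols on more than 1 line, the line with the highest mean over all arrays was kept, which left 24570 genes. Coordinates were not printed, because no build was named for the table, and genomic span and neighbouring genes were taken from GRCm38.p6.

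Changes were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), diabetic minus control, two-sided, with Benjamini-Hochberg adjustment over all 24570 genes and a threshold of 0.05. No filter on dim genes was used. Errors of changes are standard errors from limma and those of levels are SDs over 6 animals. The 42 gene lists, with 684 of their 699 members measured, were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move on balance in 1 direction. Members of a list were also adjusted over the list alone. The means of the lists for other tissues were compared with a two-sided exact permutation test over the 924 relabelings, whose smallest p is 0.00216, adjusted over 7 lists.

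The genes named in the text followed a fixed rule: the 10 largest rises and the 10 largest falls among genes past the threshold with a mean at or above the 25th percentile; Vegfa, Gfap, Icam1, Txnip, Slc2a1, Akr1b3 and Glul in any case; up to 4 members of smallest p for each list past its test; and members past the gene test for other lists. Of the genes that this rule takes, 2 are not reported here. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except where the text says that something was chosen after the data were seen. Alternatives covered the value per gene, filters on dim genes, normalization, the variance model, array weights, the replicate number as a block, thresholds, covariates, label numbers of the animals and each array left out in turn. A planned comparison of 3' and 5' control probes was not run, since control probes were not analysed here, and neither were detection calls.

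The procedure was tested on simulated data with the means and SDs of the 24570 genes and 6 arrays against 6. Of 50 genes changed by each fold, 82.0% were recovered at 1.2-fold, 82.0% at 1.3-fold, 96.0% at 1.5-fold and 100% at 2-fold, and 13 of the 193 genes called were unchanged ones. None of 40 unshifted lists was called. Both the gene and the list simulation were without correlation between genes. Each fold was added in full to the log2 values whatever the level of the gene, so recovery may be overstated for dim genes. The number of arrays limits the precision, and the table gives no signal over background for single genes.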

Results

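The series compared whole retinas of streptozotocin-diabetic mice with those of age-matched normoglycaemic mice at 6 weeks, to follow early changes of gene expression in the diabetic retina. Each group held 6 animals with 1 array each. Values were log2 RMA values of 24570 named genes, and correlations between arrays ranged from 0.993 to 0.998. The first principal component held 26.8% of the variance and parted the groups, with controls from -14.7 to -1.94 and diabetic retinas from 3.10 to 11.8 (exact permutation p = 0.00216, the smallest that the 924 relabelings allow). The animals carry label numbers whose ranges did not overlap between the groups, and what the numbers stand for is not given in the sources used here. If they mark cohorts or days, diabetes and cohort cannot be told apart.

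**Figure D1:**
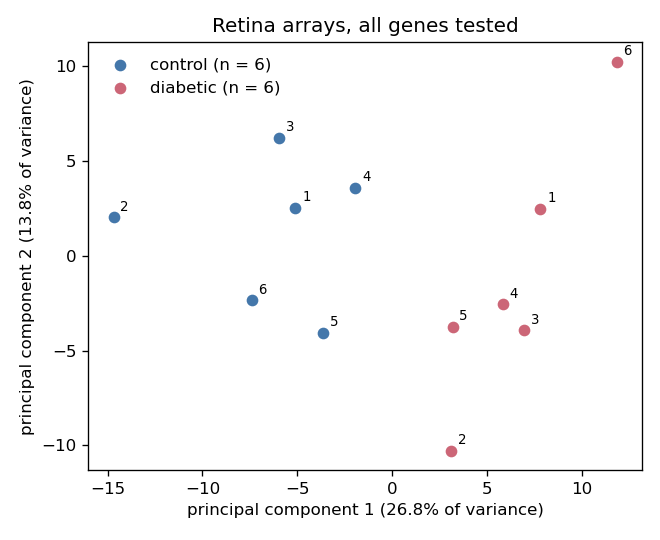
First against second principal component of the log2 values of all genes tested, in component units, with 1 point per array, numbered by replicate and coloured by group. All 6 diabetic arrays lie at 3.10 or above on the first component and all 6 control arrays at -1.94 or below.

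Diabetic retinas differed from control retinas by many small changes. Fabp4, a fatty acid-binding protein of fat cells, macrophages and endothelium, rose 1.68-fold (log2 change 0.75 ± 0.16, SE, n = 6 per group; adjusted p = 0.0346). Fkbp5, a co-chaperone induced by glucocorticoids, rose 1.38-fold (0.46 ± 0.08; adjusted p = 0.0145), and Lamc1, a laminin chain of basement membranes, rose 1.28-fold (0.36 ± 0.05; adjusted p = 0.0104). Cck, the precursor of the neuropeptide cholecystokinin, fell by 0.42 ± 0.07 on the log2 scale (adjusted p = 0.0123). All 6 diabetic arrays lay beyond the control mean for each of these genes. The genes were selected by a test on the same arrays, which makes this outcome nearly certain, so it is no separate support.

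In all, 797 of 24570 genes passed the limma test, 362 higher and 435 lower in diabetic retinas. Their median absolute change was 0.19 (1.14-fold), and 6 changed by 1.5-fold or more, 5 upward and 1 downward. The groups did not overlap for 2.84% of all genes, where chance gives 0.216%. Among the 797 genes they did not overlap for 506 (63.5%). Selection by a test on the same arrays raises this share, so it is no separate support. Of the 797, 700 were protein-coding, 49 long noncoding RNAs, 17 microRNAs and 6 small nucleolar RNAs. At an unadjusted p under 0.05 there were 5165 genes, where chance gives about 1229 on average. In the other splits drawn of the same 12 arrays into 6 and 6, this number ran from 604 to 3488. The highest came from a split that kept 5 of the 6 controls together.

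The largest rise was that of the small nucleolar RNA Snora20 (2.22-fold; log2 change 1.15 ± 0.23; adjusted p = 0.0264), followed by Mir669m-1 (0.83 ± 0.17). After Fabp4 came Zfp955b (0.70 ± 0.10), Gm15246 (0.65 ± 0.12), Gm8234 (0.58 ± 0.11), Folh1 (0.57 ± 0.14), Eef1a1 (0.56 ± 0.10), Tmem255b (0.55 ± 0.12) and Fabp9 (0.53 ± 0.11). Magea2 fell by 0.67 ± 0.16, Mir194-2 by 0.55 ± 0.12, Ighv1-75 by 0.52 ± 0.11, Spin2d by 0.50 ± 0.08 and Esp18 by 0.49 ± 0.10. Rnf123, a ubiquitin ligase, fell by 0.45 ± 0.06, the mitochondrial fission regulator Mtfr1 by 0.43 ± 0.07, Nat14 by 0.40 ± 0.06 and Snord111 by 0.40 ± 0.10. Several of these belong to families of near-identical copies (Mir669m-1, Magea2, Spin2d, Ighv1-75, Zfp955b, and Eef1a1 with its pseudogenes), whose probes may not tell the copies apart. Whether the lines for microRNAs and small nucleolar RNAs measure the mature small RNAs or other transcripts was not tested.

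**Figure D2:**
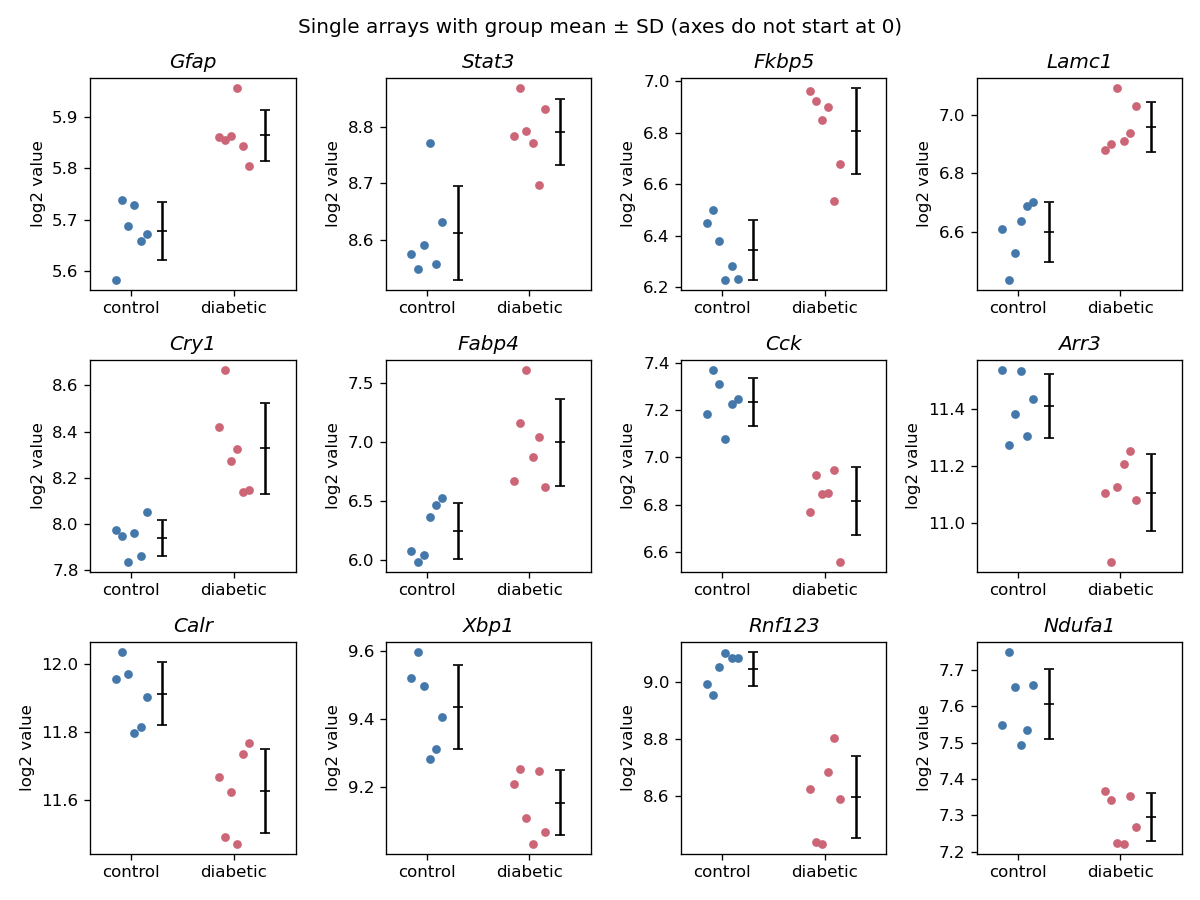
Log2 values of 12 named genes that passed the test, with 1 point per array in control (blue) and diabetic (red) retinas and the group mean ± SD over 6 animals in black. Control means lie below diabetic means for Gfap (5.68 against 5.86) and Fkbp5 (6.34 against 6.81) and above them for Cck (7.24 against 6.82) and Arr3 (11.41 against 11.11).

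Of the genes fixed in advance for diabetic retinopathy that are reported here, Gfap passed. This gene, the intermediate filament of astrocytes and reactive Mueller cells, rose 1.14-fold (0.19 ± 0.03; adjusted p = 0.0126). Its level was low, with a control mean of 5.68 close to the array median of 5.73, so the size of the rise is uncertain. Vegfa, the vascular growth factor, differed by -0.11 ± 0.04 (adjusted p = 0.160), Txnip by 0.20 ± 0.08 (adjusted p = 0.171), the glucose transporter gene Slc2a1 by 0.09 ± 0.05 (adjusted p = 0.356) and the aldose reductase gene Akr1b3 by 0.14 ± 0.05 (adjusted p = 0.143). Icam1 differed by 0.02 ± 0.02 (adjusted p = 0.749) and Glul by 0.06 ± 0.05 (adjusted p = 0.479). The control means of Icam1 (5.48) and Akr1b3 (5.43) lay below the array median of 5.73. For these dim genes, a missing call does not show that they were unchanged.

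The count depended on single arrays. It was 325 genes without diabetic replicate 4, 339 without diabetic 3, 428 without diabetic 1 and 454 without diabetic 6. It was 393 without control 2, 395 without control 3, 428 without control 6 and 464 without control 1. All 797 genes kept their direction without any single array, but genes selected on these same arrays could hardly turn. Among the named genes, Cck, Creld2, Eef1a1, Fkbp5, Gfap, Gm15246, Lamc1, Mtfr1, Nat14, Ndufa1, Rnf123, Sdha, Spin2d and Zfp955b passed without any single array. The other 34 of the 48 that passed lost the call in at least 1 such run. Folh1, Magea2, Rdh8 and Snord111 lost it in 11 of the 12 runs. Arc, Bag3, Car8, Dab1, Dhcr7, Gngt1, Hsp90aa1, Septin4 and Stat3 lost it in 10. Acta2 lost it in 9, and Arr3, Cpt2 and Mpo were among those that lost it in 8. Asns and Xbp1 were among those that lost it in 7, Calr and Fabp4 in 6, and Cry1 in 5. At the other end, Ndufa5 was among those that lost it in 2.

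Of the gene lists, 3 passed the test against all other genes with a preset correlation, clock genes upward and endoplasmic reticulum stress genes and immediate early genes downward in diabetic retinas, but none of them passed with an estimated correlation, and few of their members passed over all genes. All 17 clock genes had values above 0 (median log2 change 0.07), of which 1 passed over all genes and 6 adjusted over the list alone. Cry1, a repressor of the clock, rose 1.31-fold (0.39 ± 0.08; adjusted p = 0.0291), whereas Arntl (0.09 ± 0.03; adjusted p = 0.0893), Per2 (0.14 ± 0.04; adjusted p = 0.0912) and Clock (0.11 ± 0.04; adjusted p = 0.119) did not pass over all genes. The list had an adjusted p of 0.000425, and adjusted p = 0.588 with an estimated correlation.

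Of the 20 endoplasmic reticulum stress genes, 15 had values below 0 (median -0.09), 4 fell over all genes, and 6 fell and 1 rose adjusted over the list alone. Creld2 fell by 0.30 ± 0.05 (adjusted p = 0.0126), asparagine synthetase (Asns) by 0.29 ± 0.06 (adjusted p = 0.0334), the chaperone calreticulin (Calr) by 0.29 ± 0.06 (adjusted p = 0.0286), and Xbp1, a transcription factor of the unfolded protein response, by 0.28 ± 0.06 (adjusted p = 0.0310). The list had an adjusted p of 0.00667, and adjusted p = 0.648 with an estimated correlation.

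Of the 15 immediate early genes, which respond within minutes to neuronal activity and other stimuli, 14 had values below 0 (median -0.06), with 1 past the test over all genes and 4 adjusted over the list alone. Arc fell by 0.13 ± 0.03 (adjusted p = 0.0462), and Nr4a1 (-0.40 ± 0.12; adjusted p = 0.0840), Egr1 (-0.31 ± 0.11; adjusted p = 0.122) and Fos (-0.26 ± 0.07; adjusted p = 0.0598) did not pass over all genes. The call of Arc was lost in 10 of the 12 runs that left out 1 array. The list had an adjusted p of 0.00667, and adjusted p = 0.588 with an estimated correlation. None of the 3 list calls held with an estimated correlation or with fry (adjusted p = 0.0702 for clock genes and 0.0532 for each of the others). In 71 of 100 splits of the same 12 arrays into 6 and 6, the real one included, 3 or more lists passed, so the number of lists does not set the groups apart from other splits.

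**Figure D3:**
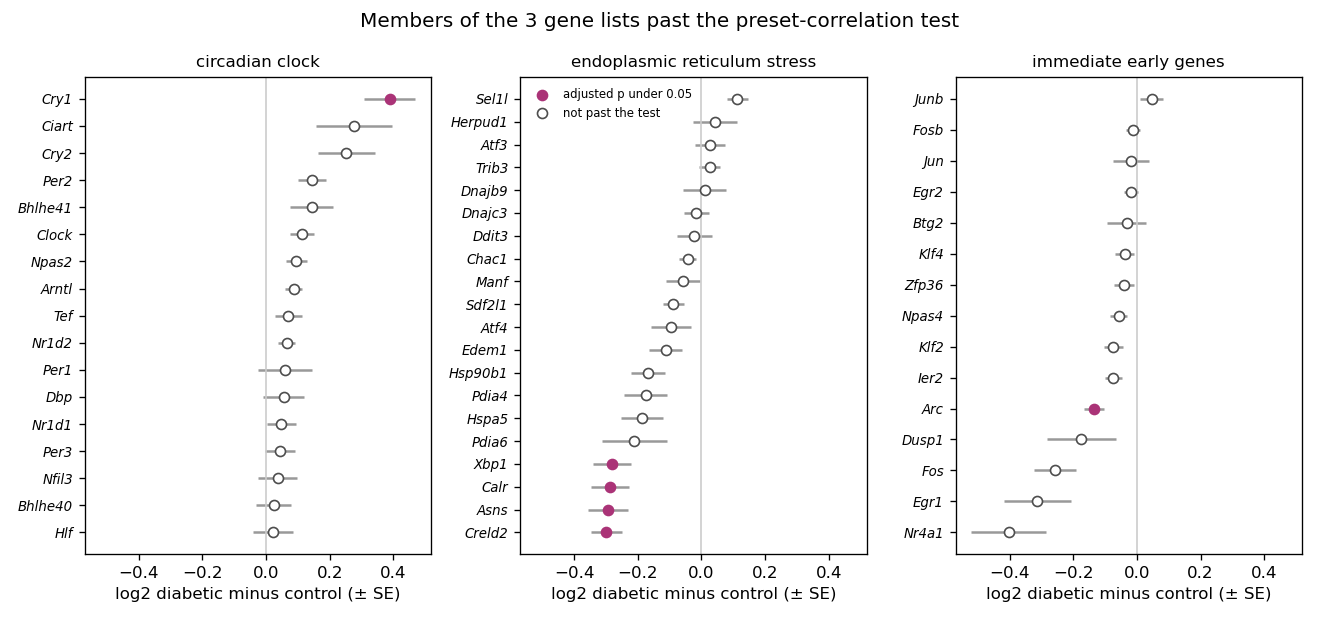
Log2 change (diabetic minus control) of each measured member of 3 gene lists, with SE as bars, n = 6 per group. Filled points passed the test over all genes: Cry1 at 0.39 among clock genes, 4 endoplasmic reticulum stress genes between -0.30 and -0.28, and Arc at -0.13 among immediate early genes.

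Glial reactivity genes missed the list threshold (adjusted p = 0.0541), with 2 of 16 higher over all genes and 3 adjusted over the list alone. Beside Gfap, Stat3, a transcription factor of glial activation, rose by 0.18 ± 0.04 (adjusted p = 0.0351). Neurotrophic factors and receptors missed it too (adjusted p = 0.0505), with 12 of 14 below 0 and 0 past the gene test, whether over all genes or adjusted over the list alone. In exact permutation tests of the list means, which were not planned for process lists, these 2 lists and the 3 above each had an adjusted p of 0.0498 over the 23 process lists, but none of the 5 passed camera with an estimated correlation (adjusted p = 0.588 for glial reactivity and for neurotrophic factors).

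No retinal cell type list passed the list test, and the members that passed over all genes fell. The smallest p of the exact permutation tests of their means, not planned for these lists either, was that of horizontal cells (p = 0.00649, adjusted p = 0.0649). Among 12 cone genes (list adjusted p = 0.110), cone arrestin (Arr3) fell by 0.30 ± 0.07 (adjusted p = 0.0348), the only one over all genes and 1 of 2 adjusted over the list alone. Among 14 rod genes (0.493), Gngt1, a transducin subunit, fell by 0.29 ± 0.07 (adjusted p = 0.0430), with 3 lower adjusted over the list alone. Among 14 bipolar cell genes (0.541), Bhlhe23 fell by 0.27 ± 0.06 and Car8 by 0.18 ± 0.04, while 5 were lower and 2 higher adjusted over the list alone. Dab1 of amacrine cells fell by 0.25 ± 0.06, Septin4 of horizontal cells by 0.24 ± 0.06 and Acta2 of pericytes and smooth muscle by 0.21 ± 0.05, each the only one of its list both over all genes and adjusted over the list alone. Over all genes, each of these named calls was lost in 6 (Bhlhe23) to 10 of the 12 runs that left out 1 array. No gene of the ganglion cell, endothelial or microglia lists passed by either adjustment. The microglia list was dim, with a control mean of 5.79, close to the array median of 5.73. In the Mueller glia list 0 of 12 passed over all genes, and 1 was higher and 1 lower adjusted over the list alone.

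In the oxidative phosphorylation list (35 genes, adjusted p = 0.660), members went both ways: the complex I subunits Ndufa1 (-0.31 ± 0.05), Ndufv2 (-0.15 ± 0.03) and Ndufa5 (-0.13 ± 0.03) fell, and Ndufv1 (0.17 ± 0.04) and the succinate dehydrogenase subunit Sdha (0.13 ± 0.02) rose, the same number by either adjustment. Single members of other lists passed as well. Cpt2 of fatty acid oxidation fell by 0.19 ± 0.04, Dhcr7 of cholesterol synthesis by 0.19 ± 0.04, the visual cycle gene Rdh8 by 0.16 ± 0.04 and the co-chaperone Bag3 by 0.15 ± 0.03, while Hsp90aa1, at a low level of 5.45, rose by 0.21 ± 0.05. Adjusted over the list alone, 2 visual cycle genes were lower and 1 higher, 3 heat shock genes were lower and 1 higher, and the lists of Cpt2, Dhcr7, Lamc1 and Fkbp5 each held 1 gene by either adjustment. Hypoxia and angiogenesis, inflammatory cytokine, complement, antioxidant, glycolysis and polyol pathway lists held 0 genes past the test over all genes or adjusted over the list alone. The control means of the inflammatory cytokine (5.80) and complement (5.83) lists lay close to the array median of 5.73. For these dim lists, 0 calls do not show that the genes were unchanged. In 9 lists, all with an adjusted p of 0.656 or more, the median, the mean and the test differed in sign.

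Markers of tissues next to the retina varied between arrays without parting the groups. Crystallins, the proteins of the lens, averaged 6.09 ± 0.23 in controls and 6.31 ± 0.58 in diabetic retinas (SD, n = 6; exact permutation p = 0.437, adjusted p = 0.830), with the highest means in diabetic 6 (7.24) and diabetic 2 (6.78). Other lens fibre markers differed by 0.04 (exact permutation p = 0.474), and pigment epithelium markers by 0.02 (exact permutation p = 0.911). Red blood cell, skeletal muscle and cornea lists gave exact permutation p of 0.626, 0.974 and 0.474. Lymphocyte and neutrophil markers were lower in diabetic retinas by a small amount (5.38 ± 0.01 against 5.41 ± 0.01; exact permutation p = 0.00216, adjusted p = 0.0152), at a level below the array median of 5.73, but the list did not pass camera (adjusted p = 0.204 with the preset and 0.588 with an estimated correlation). Mpo was its one member past the gene test (-0.07 ± 0.02; adjusted p = 0.0367). With the median over the list in place of the mean, none of the 7 lists passed.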

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

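The tests of lens carryover, of genomic span and of time of day were chosen after the results were seen; the splits of the arrays were planned before their result was seen. Among 204 groups of 6 arrays (named genes and list means), 11 had 1 array far from the other 5 by the ratio of gap to range (above Dixon's 95% critical value), 5.39%, where chance gives about 1 in 20. In controls these were Tmem255b (ratio 0.864, control 3, low), Akr1b3 (0.807, control 2, high), Hsp90aa1 (0.757, control 3, high), Per2 (0.735, control 1, low), Clock (0.733, control 5, high), Icam1 (0.632, control 3, high) and Stat3 (0.632, control 4, high). In diabetic retinas they were Mpo (0.736, diabetic 6, low), Asns (0.634, diabetic 2, low), the apoptosis list (0.672, diabetic 2, high) and the lens fibre list (0.768, diabetic 6, high).

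The count of 797 genes was reached by 1 of 100 splits of the 12 arrays, the real one, with at most 1 gene in any other. A chance split is thus unlikely to give this count, although only 100 of the 462 splits were drawn. This concerns the size of the count and not each gene in it. Carryover of lens and pigment epithelium, which was highest in diabetic 6 (Cryaa 11.73, Dct 8.61), would need the changes to shrink once it is adjusted for, but the median ratio of the adjusted to the unadjusted change over the 797 genes was 1.02 ± 0.08 (median absolute deviation). The lens fibre and pigment epithelium means differed between groups by 0.04 and 0.02, so this ratio could hardly fall and decides little. With the trend with genomic span removed, the ratio was 0.975 ± 0.04. That trend was small: median changes were -0.03 in the shortest 20% of brighter genes and 0.02 in the longest. The called genes had a median absolute change of 0.19. This size argues against the trend as the whole cause, and the ratio adds little to it. Cohort, day of collection or array batch behind the label numbers stays open beside diabetes, since none of them can be separated from the groups.

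The number of 3 lists was reached by 71 of 100 splits, with up to 13 lists in another split, so chance cannot be excluded for it. For clock genes, a span trend is argued against as the whole cause by a ratio of 1.05 of the list's median with the trend removed to that without. A difference in the time of day at collection could move clock genes, and would then move the activator and output arms apart. Arntl, Npas2 and Clock were higher by 0.10 (exact permutation p = 0.00649) and Dbp, Nr1d1, Per1, Per3, Tef and Hlf by 0.05 (exact permutation p = 0.234), so the second arm decides nothing and time of day cannot be told apart from diabetes. Handling at death, which might change immediate early genes, was not tested.

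Long genes tended to be higher and short genes lower in diabetic retinas. Among genes at or above the median level, the shortest 20% held 32 higher and 109 lower genes past the test and the longest 78 and 36. The slope of single arrays on log2 span differed between groups by 0.0025 (exact permutation p = 0.0411), but single arrays overlapped. Diabetic 4 (0.0035) and diabetic 6 (0.0034) were highest, and control 2 (-0.0031) and control 1 (-0.0029) lowest. Control 4 (0.0011) lay above diabetic 3 (0.0005), diabetic 5 (-0.0004) and diabetic 2 (-0.0007). Brightness may contribute: the slope passed in 1 of 3 tertiles of level, the brightest (0.0067, exact permutation p = 0.0303), and missed in the middle one (0.0030, exact permutation p = 0.0779), while the dimmest lies near the floor. RNA quality or labelling cannot be told apart from diabetes, because a difference between groups fits either.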

How the results depend on the processing

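The runs without 2 arrays together and the run with the trend on genomic span removed were chosen after the data were seen; all others were planned. The 797 genes kept their direction in every run that tested them. Since they were selected on the same arrays, this says little about stability. The count was 893 and 835 with dim genes left out at the 25th percentile and the median, 895 with trend and robust eBayes, 903 with array weights and 1118 with lens and pigment epithelium covariates (644 of the 797 among them). It moved to 1967 at adjusted p 0.10, to 6 with a fold of 1.5 as well, and to 506 with the replicate number as a block (349 shared). Same-numbered animals correlated from -0.17 to 0.18 in their deviations, and 1 of 6 controls correlated best with its own number. These values gave little sign that the numbers pair the animals, but they cannot exclude a pairing. With the 4 diabetic animals of lower label numbers 291 genes passed (246 shared). With the 2 of higher numbers 0 passed (limma, 3423 at an unadjusted p under 0.05). Fewer arrays give less power, but some changes were also smaller in these 2 animals, such as those of Snora20, Fkbp5, Cry1 and Folh1. Others, such as that of Gm15246, were not. Without control 2 and diabetic 6 the count was 236, and without diabetic 2 and diabetic 6 it was 379. Without single arrays it ranged from 325 to 835, moving by over 1.5 times without control 1, 2, 3 or 6 or diabetic 1, 3, 4 or 6 (464, 393, 395, 428, 428, 339, 325 and 454). With the span trend removed it was 750 (710 shared). The number of lists was 0 with an estimated correlation (2 lists at an unadjusted p under 0.05), 5 with the span trend removed, and from 3 to 6 without single arrays (5 without control 1, control 4 or diabetic 5, and 6 without diabetic 4); fry gave 2 lists, neurotrophic factors and lymphocyte markers, none of them among the 3. The number of other tissue lists was 0 with the median over the list and 1 without any single array. The cause of these moves was not tested unless stated. Of 1294 values of the 48 named genes that passed, 845 stayed past the threshold, 449 did not, and 0 reversed; 11 of the genes lost the call only with the higher label numbers. Of 322 values of the other named genes, 9 passed (Akr1b3, Clock, Fos and Nr4a1). Quantile normalization once more, centring and the mean of lines moved no call and say nothing about stability. The 3' to 5' comparison and covariate were not run.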

Other observations

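All groups and genes in this part were chosen after the data were seen, so their tests describe hypotheses found in these data. The protocadherin beta genes, neighbours on 1 chromosome that encode neuronal adhesion molecules, moved together: 21 of 22 had values above 0 (median 0.14), and 5 rose (Pcdhb19 by 0.33 ± 0.04, Pcdhb21 by 0.30 ± 0.05, Pcdhb12 by 0.27 ± 0.05, Pcdhb20 by 0.26 ± 0.04 and Pcdhb18 by 0.21 ± 0.05; SE, n = 6 per group). Of the 17 others, without the 5 that prompted the group, 16 were above 0 (median 0.11), and camera gave p = 3.1e-06 with the preset and p = 0.0112 with an estimated correlation, unadjusted. Of the gamma cluster 16 of 22 were above 0 (p = 0.500 with an estimated correlation) and of the alpha cluster 7 of 14 (p = 0.640). No gene of the gamma cluster passed, and in the alpha cluster Pcdha11 fell by 0.34 ± 0.07 (adjusted p = 0.0255). The genes are similar in sequence, and whether their probes are shared was not tested.

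Fabp4 (0.75), Fabp9 (0.53) and Pmp2 (0.27 ± 0.04; adjusted p = 0.0104), which lie side by side, rose, while the nearby Fabp5 (0.00) and Fabp12 (-0.04) did not pass. Over the genome, 26 pairs of neighbours both passed, against a mean of 25.9 in 1000 shuffles. Nr3c1, the glucocorticoid receptor, fell by 0.21 ± 0.04 (adjusted p = 0.0264) where its target Fkbp5 rose. Serpina3n (0.49 ± 0.14, adjusted p = 0.0858) and Lcn2 (0.51 ± 0.20, adjusted p = 0.177) are acute-phase genes of the glial reactivity list. Both were above the control mean in 6 of 6 diabetic arrays but did not pass. The Lcn2 change leaned on diabetic 2 (8.40). The other diabetic arrays lay from 7.01 to 7.34, and the highest control, control 1, at 7.02. Outside the fixed lists, the single genes Pdia3 and Kdelr1 of the secretory pathway fell by 0.29 ± 0.05 and 0.26 ± 0.05, and the cytosolic chaperone Hsp90ab1 by 0.27 ± 0.05.

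Utp20, Wdr3, Wdr43 and Nol11, parts of the small subunit processome that assembles ribosomes in the nucleolus, rose by 0.28 ± 0.04, 0.31 ± 0.05, 0.22 ± 0.03 and 0.18 ± 0.04. The other 36 processome genes may share this shift: 26 were above 0 (median 0.08), with p = 0.000989 by camera with the preset correlation but p = 0.124 with an estimated one, so it stays open. Mitochondrial ribosomal protein genes gave no such hint. Beside Mrps6, Mrps16, Mrps23 and Mrpl48, which rose, 34 of 72 others were above 0 (p = 0.891 with an estimated correlation). Of 98 small nucleolar RNAs 5 were higher and 1 lower, of 38 proteasome subunits 1 was lower, and of 1091 olfactory receptors 5 were lower. By camera these 3 families gave p of 0.000125, 0.590 and 0.317 with the preset correlation and 0.241, 0.765 and 0.253 with an estimated one, and by exact permutation of their means 0.143, 0.390 and 0.0108. Of the small nucleolar RNAs 69 were above 0 (median 0.05), and of the olfactory receptors 474 (median 0.00), and whether either family shifted stays open.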
